A study of Meloidogyne incognita with 6 samples.

How the data were processed

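The series holds RNA sequencing of wild-type second-stage juveniles (J2) of the southern root-knot nematode Meloidogyne incognita, a plant parasite whose J2 hatch from the egg, move through soil and enter roots. Per the labels, 6 libraries were made from total RNA extracted with Trizol, by standard Illumina library preparation: 3 from an early and 3 from a middle stage of the J2. The labels do not say how the stages were defined, and nothing in them says that the 3 replicates of a stage came from separate cultures. The p-values below therefore measure the spread between these libraries, which may be technical.

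The deposited table gives FPKM values (fragment counts scaled by the length of the gene model and by the number of counted reads) for each library separately, per the file header. Per the submitters' processing notes, CASAVA and TopHat2 were used. Their versions, the read counter, the genome build, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The table has 20365 gene rows, identified only by IDs that start with Minc. It pairs these IDs with no symbol, product, position or sequence, and no genome or annotation was used here. The 26 gene lists drawn up for this comparison could therefore not be applied, and no gene list test was run. A further 16 columns have no name, and 8 of them hold numbers in 8 gene rows. They match no sample and were not used.

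The FPKM values step in whole multiples of the value of a single read. The ratios of low values between libraries gave the relative depths, and the requirement of whole counts and whole lengths gave the denominators, the read count of every row and a length for every gene model. All 17197 rows above 0 in at least 1 library came out as whole counts, with 100% of the values within 0.001 of a whole number. Each length was picked so that the counts of its row came out whole. This closeness therefore follows from the search and does not test the counts. The denominators came out within 0.00114 of whole numbers. The recovered reads of the rows summed to 99.64% to 99.66% of the denominators. On 8000 simulated rows the procedure returned all 6 denominators, and the right counts in 98.73% of the rows with reads. All simulated lengths were multiples of 3 and none reached the longest recovered lengths, so recovery of such models was not tested. Counts of a row that share a common factor come out too low, together with its length. A recovered count may stand for a read or a read pair. Of the recovered lengths, 77.7% were multiples of 3, and the median was 900.0 bases. The denominators ranged from 5305983 to 7436406 reads. A gene model of 1 kilobase was worth 0.134 to 0.188 FPKM per read, and the 3 reads that a count of 0 allows correspond to 0.403 to 0.565 FPKM. Counting intervals are exact 95% binomial intervals and cover counting error only.

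The gene lists, the main test, the rule for naming rows and the first group of alternatives below were set before the data were examined. Rows with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1), with FPKM as deposited, by limma 3.58.1 (linear model on stage, empirical Bayes with an intensity trend) in R 4.3.3. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low rows, and are given as middle minus early. Single values per library were compared by an exact permutation test, which cannot go below 0.1 with 3 against 3. The rows named by ID were set by the rule for IDs paired with no names: the 2 largest rises and the 2 largest falls among rows past the threshold with non-overlapping stages.

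The limma procedure was tested on simulated data for the middle against early comparison. Negative binomial counts were drawn from the real means and depths, and 13165 simulated rows reached the mean of 1 FPKM and were tested, with a biological coefficient of variation of 8.8%, and 67, 67 and 66 rows were changed by 1.5, 2 and 4-fold in either direction. It recovered 40.3% of the 1.5-fold, 71.6% of the 2-fold and 87.9% of the 4-fold changes, with 7 false calls among 140. All simulated rows shared the same coefficient of variation. Real rows may vary more and unequally, so these rates hold for the simulated setting and may be too favourable.

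The first group of alternatives held pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, 3 other scalings, no trend, sample weights, a 2-fold minimum, the replicate number as a block, and leaving out each library in turn. A further group, chosen after seeing the data, held limma voom on the recovered reads in 3 forms (rows with at least 10 reads in all), rows without sibling IDs, and removal of the trend with length. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.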

Results

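Gene expression was measured in early and middle J2 of M. incognita, with 3 libraries per stage. The FPKM denominators were 5772231, 5637924 and 7436406 reads in early replicates 1 to 3, and 5305983, 6523712 and 6096805 reads in middle replicates 1 to 3. Mean depth did not differ detectably between the stages (exact permutation test, two-sided, p = 0.7). Each library had between 15172 and 15693 gene rows above 0 and between 12973 and 13122 rows at or above 1 FPKM. The number of rows at or above 1 FPKM was 13053 ± 75 in early and 13010 ± 25 in middle J2 (SD, n = 3; exact permutation p = 0.5). In all 6 libraries 3168 rows were listed at 0.

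The libraries separated by stage. Over the 13142 rows with a mean of at least 1 FPKM, Pearson's r of log2(FPKM + 1) across rows was 0.976 to 0.983 between early libraries and 0.968 to 0.977 between middle libraries. It was 0.926 to 0.945 between libraries of different stages. The first principal component held 62.6% of the variance and parted the stages. Middle replicate 3 lay at 27.71 on this component, against 43.96 and 41.75 for the other middle libraries. Every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.70 to 14.42, so no library appeared to have been entered more than once.

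**Figure D1:**
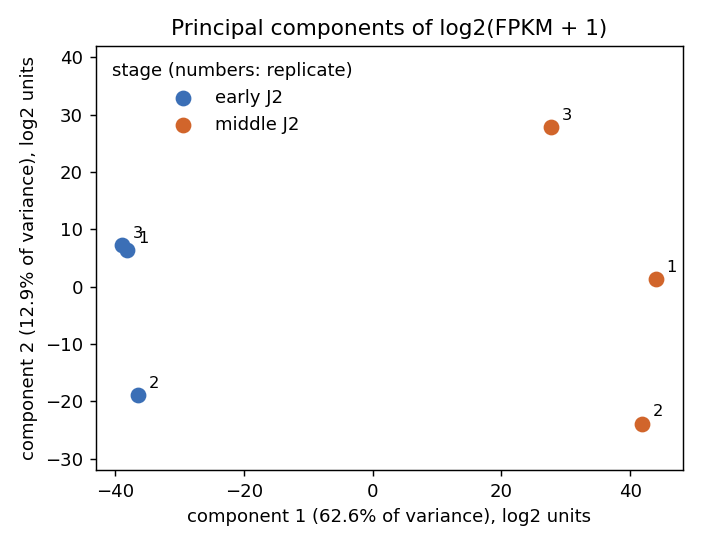
Principal components of log2(FPKM + 1) over the 13142 tested rows, with component 1 (62.6% of the variance) on the horizontal and component 2 (12.9%) on the vertical axis, both in log2 units; each point is a library and the numbers are replicates. Early libraries lie between -38.83 and -36.48 on component 1 and middle libraries between 27.71 and 43.96.

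The comparison of middle with early J2 asked which transcripts change within this juvenile stage. Of the 13142 rows tested, 2421 (18.4%) differed, and 1225 of these were higher and 1196 lower in middle J2 (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were moderate: the median log2 fold change was 0.79 among the rows that rose and -0.69 among those that fell. At least a 2-fold change was reached by 437 rows that rose and 382 that fell. At least 8-fold changes numbered 45 rises and 59 falls, and at least 16-fold changes 13 rises and 32 falls. These 8-fold and 16-fold counts hold for the log2(FPKM + 1) scale, which understates the change of low rows. They were not recounted with smaller pseudocounts, so the excess of strong falls may depend on this scale.

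The stages did not overlap in 2418 of the 2421 rows past the threshold. They did not overlap in 38.4% of all tested rows, against 10% by chance for 3 against 3 libraries. The balance of rises and falls depended on the scale: with each library rescaled to the same FPKM sum, 1009 rows were higher and 1538 lower, so that 39.6% of the calls were rises against 50.6% on the deposited scale. Leaving out any 1 library gave fewer calls, and the count moved by over 1.5 times in 3 cases: 1362 rows passed without middle replicate 1, 1456 without early replicate 1 and 1503 without early replicate 3. No batch is given by the labels, so a batch that followed the stages could not be told apart from them.

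**Figure D2:**
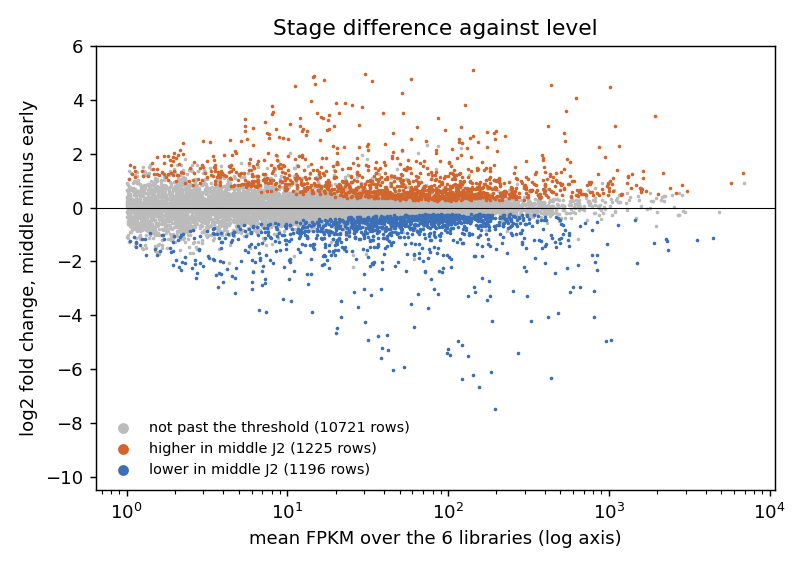
Log2 fold change (middle minus early, on the log2(FPKM + 1) scale) against the mean FPKM over the 6 libraries (log axis) for the 13142 tested rows; each point is a gene row, coloured by the limma call. The 1225 rises and 1196 falls spread over the whole range of levels, and on this scale the falls reach larger sizes than the rises.

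On the log2(FPKM + 1) scale the largest fall was that of Minc09098, a gene model of 654 bases. Its level was 390 ± 55.9 FPKM in early J2 and 1.20 ± 0.528 FPKM in middle J2 (SD, n = 3), resting on 4877 and 14 reads. Its log2 fold change was -7.49 with a standard error of 0.19 (limma, adjusted p = 1.24e-06). Minc19126, of 837 bases, fell from 309 ± 86.5 to 2.13 ± 1.09 FPKM (SD, n = 3), with 5017 reads in early and 33 in middle J2. Its log2 fold change was -6.66 with a standard error of 0.30 (limma, adjusted p = 1.77e-05). By mean FPKM the early level was 324 times the middle level for Minc09098 and 145 times for Minc19126. Read counts scaled by depth gave middle-to-early ratios of 0.00302 (95% interval 0.00165 to 0.00507) and 0.00692 (0.00476 to 0.00972).

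On the same scale the largest rise was that of Minc00222, of 1135 bases, from 6.89 ± 1.51 FPKM in early to 279 ± 105 FPKM in middle J2 (SD, n = 3). It rested on 144 and 5602 reads and had a log2 fold change of 5.09 with a standard error of 0.29 (limma, adjusted p = 5.47e-05). Minc08325, of 893 bases, rose from 0.855 ± 0.219 to 60.4 ± 25.3 FPKM (SD, n = 3), with 14 reads in early and 961 in middle J2. Its log2 fold change was 4.95 with a standard error of 0.33 (limma, adjusted p = 1.11e-04). Scaled by depth, middle J2 had 40.9 times the reads of early J2 for Minc00222 (95% interval 34.7 to 48.6) and 72.2 times for Minc08325 (42.8 to 132.5). In middle replicate 3 both rows stood near the midpoint of the rise on the linear FPKM scale, though not on the log2 scale. They were at 165 FPKM for Minc00222 against 373 and 299 FPKM in the other middle libraries, and at 31.2 FPKM for Minc08325 against 75.8 and 74.2 FPKM. These ranks depend on the pseudocount. With a pseudocount of 0.1 Minc08325 ranked 9 and Minc00222 ranked 16 among the rises, with Minc09098 still at 1 and Minc19126 at 3 among the falls. With 0.01 the ranks were 20 and 30 among the rises and 6 and 15 among the falls. What these 4 rows encode is not analysed here. Reads shared with near-identical gene copies could not be separated in any row.

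**Figure D3:**
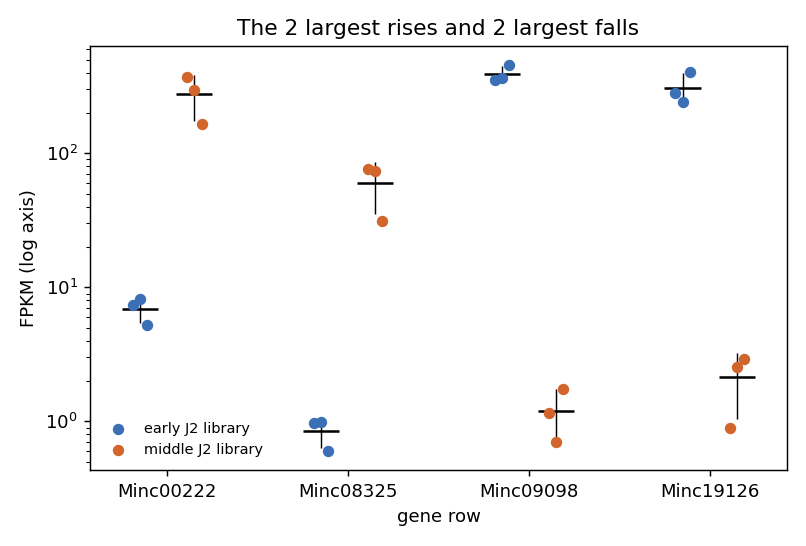
FPKM (log axis) of the 2 rows with the largest rise and the 2 with the largest fall on the log2(FPKM + 1) scale; each point is a library, horizontal bars are stage means and vertical lines ± 1 SD (n = 3). Minc09098 and Minc19126 lie at or above 240.7 FPKM in every early library and below 3 FPKM in every middle library, and in Minc00222 and Minc08325 every middle library lies above every early one.

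Rows with strong falls and strong rises differed in their early level, which choosing rows by their change largely fixes. A strong fall needs the higher level in early J2 and a strong rise needs it in middle J2. The log2(FPKM + 1) scale adds to this, since a strong fall on it needs a high early level. The 59 rows that fell by at least 8-fold had a median early level of 144 FPKM and a median middle level of 5.03 FPKM. Together they held 2.11 ± 0.282% of the FPKM sum in early and 0.121 ± 0.0568% in middle J2 (SD, n = 3). The 45 rows that rose by at least 8-fold had medians of 1.88 FPKM in early and 38.8 FPKM in middle J2. Their share of the FPKM sum was 0.130 ± 0.0511% in early and 1.43 ± 0.0852% in middle J2 (SD, n = 3). All rows that rose held 15.2 ± 0.366% of the sum in early and 26.8 ± 0.896% in middle J2, and all rows that fell held 19.4 ± 1.20% and 9.16 ± 0.481% (SD, n = 3). These rows were chosen for their change in the same libraries, so the shares describe its size and do not test it.

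Changes were found in every band of mean level, and the share of rows past the threshold rose with level and depth. Of the 1969 rows at a mean of 100 FPKM and above, 424 rose and 325 fell, so that 38.0% were past the threshold. Between 20 and 100 FPKM, 469 of 5740 rows rose and 590 fell (18.4%). Between 5 and 20 FPKM, 226 of 2984 rows rose and 199 fell (14.2%). Of the 2449 rows between 1 and 5 FPKM, 106 rose and 82 fell (7.7%). The median depth was 1044 reads per library in the highest of these bands and 10 reads in the lowest. Calls of at least 2-fold did not follow this order. They were 10.1% of the rows at 100 FPKM and above, 4.1% between 20 and 100 FPKM, 7.5% between 5 and 20 FPKM and 6.5% between 1 and 5 FPKM.

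The most abundant transcripts held a larger share of every middle library than of any early library, a difference for which the exact permutation test cannot reach a p under 0.05 with 3 against 3 libraries. The 10 rows with the highest mean level held 4.43 ± 0.454% of the FPKM sum in early and 5.16 ± 0.143% in middle J2 (SD, n = 3; exact permutation p = 0.1, the smallest possible). For the 100 highest rows the shares were 18.3 ± 1.06% and 21.2 ± 0.132% (SD, n = 3; exact permutation p = 0.1). The highest single value was 5662.1 to 6423.1 FPKM in the early and 9501.4 to 10872.7 FPKM in the middle libraries. The FPKM sum itself was 896521 ± 8777 in early and 939187 ± 6724 in middle J2 (SD, n = 3; exact permutation p = 0.1).

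Short and long gene models differed in the direction of change. The tested rows were parted by length into 5 bands of near equal size. Among the 2631 rows of the shortest band (36 to 453 bases), 361 rose and 186 fell. Among the 2625 rows of the longest band (1736 to 18213 bases), 138 rose and 260 fell. The odds of a rise among the calls in the shortest band were 3.66 times those in the longest band (Fisher's exact test over rows, two-sided, p = 1.07e-21; rows are not independent replicates). The median log2 fold change of all rows went from 0.105 in the shortest to -0.073 in the longest band. A shift of this size can turn the direction of small changes only. Among calls of at least 2-fold, 140 rises and 108 falls lay in the shortest band and 57 rises and 44 falls in the longest, so that 56.5% and 56.4% were rises (Fisher's exact test over rows, two-sided, odds ratio 1.0).

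**Figure D4:**
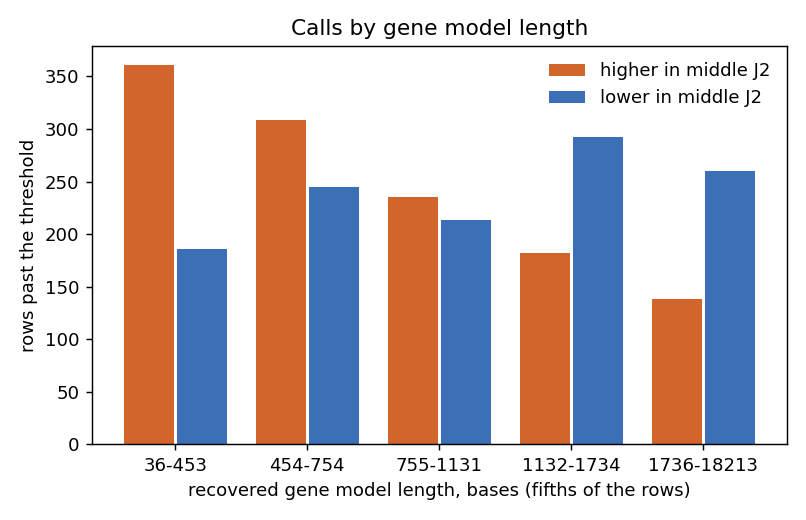
Number of rows past the threshold in each of 5 bands of the tested rows by recovered gene model length in bases; bars start at 0 and show rows higher and rows lower in middle J2. Rises go from 361 in the shortest to 138 in the longest band, and falls from 186 to 260, with the most falls, 292, between 1132 and 1734 bases.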

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

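The voom fits, the fit on rows without sibling IDs and the removal of the length trend were chosen after seeing the data, and the other alternatives before. The 2421 calls ranged from 819 to 2939 over 22 alternative settings, and no call changed its direction under any of them in which it was tested. This was largely fixed in advance, since the stages did not overlap in 2418 of the calls. For those, only another scaling, voom or removal of the length trend could have turned the direction. Requiring a 2-fold change left 819 calls (437 higher, 382 lower) by construction. Leaving out a library gave 1362 to 2263 calls, with 671 to 1143 higher and 691 to 1120 lower. The lowest counts came without middle replicate 1 (1362), early replicate 1 (1456) and early replicate 3 (1503), each with fewer libraries by construction, and 55.3%, 58.3% and 59.8% of the calls remained. The other 18 settings stayed within 1.5 times of the main count. Voom on the recovered reads gave 2508 calls, sharing 2182 with the main test, and pseudocounts of 0.1 and 0.01 gave 2371 and 2314. The share of rises lay between 48.6% and 53.6%, except after rescaling to a common FPKM sum (39.6%), which moved the median log2 fold change by -0.065. The 4 named rows kept their direction and passed the threshold under all 21 alternatives run on them, with adjusted p from 5.3e-07 to 0.00735, the highest from voom with median-ratio size factors. Counting rows at or above 0.1 FPKM gave a middle-minus-early difference of -173 in place of -43. The top 100 rows gave a share difference of 2.91 in place of 0.735 percentage points. No test passed its threshold, which the exact permutation test cannot reach with 3 against 3 libraries. With the replicate number as a block 2187 rows passed (1120 higher, 1067 lower), and 2005 of the calls remained. Deviations of same-numbered libraries correlated at 0.005, 0.089 and 0.120, and other pairs at -0.153 to 0.077. Early replicates 2 and 3 correlated best with their own number, but early replicate 1 did so with middle replicate 3 (0.057) and middle replicate 1 with early replicate 2 (0.077), so a pairing by number is not shown for every library. Of the 10 splits of the 6 libraries into 3 and 3, only the real one, counted as 1, gave 2421 calls. The highest other gave 16. Every other split mixed both stages in each group, so the stage difference itself widened the spread and held the calls down. Their low counts are therefore no measure of chance, and 10 splits are too few for a share under 0.05. The planned gene list tests and their alternatives were not run, because the IDs are paired with no names. Depth limits the low rows, which had a median of 10 reads per library between 1 and 5 FPKM.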

Other observations

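The tests in this part were chosen after the result was seen, and removal of the length trend after the trend was seen but before its calls were counted. Few rows had reads in every library of a single stage only. In early J2, 46 rows had no read while all 3 middle libraries had at least 1, with a median of 4.5 and at most 389 reads over the middle libraries. In middle J2, 64 rows had no read while all 3 early libraries did, with a median of 7.0 and at most 98 reads over the early libraries. The other 18 choices of 3 libraries, which mix the stages, gave 18 to 51 such rows, so the 46 rows lay within the range that mixed choices gave and the 64 rows above it. With the 3 reads that a count of 0 over a stage allows, the median bound on the fold was 1.58 for the first set and 2.22 for the second.

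The 1928 rows whose IDs share a stem and differ in a final letter were listed at 0 in all 6 libraries in 1316 cases (68.3%), against 1852 of the 18437 other rows. Of the 775 such stems, 292 had every row at 0, 357 a single row above 0 and 126 at least 2 rows above 0. A level listed at 0 for such a row does not show that the gene was silent.

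Middle replicate 3 lay between the other middle libraries and the early libraries. For rows that changed by at least 8-fold, chosen without the library in question, its median position between the early mean (0) and the mean of the other middle libraries (1) was 0.78 for 50 rises and 0.80 for 58 falls on the log2 scale. A mixture with early-stage RNA would give rises and falls the same position on the linear FPKM scale. These were 0.49 and 0.97, a difference of 0.49 (bootstrap over rows, 95% interval 0.25 to 0.56 over 2000 draws). This argues only weakly against a mixture as the whole cause, since the bootstrap over rows does not cover variation between libraries. The same difference lay between -0.23 (early replicate 3) and 0.31 (early replicate 2) in the other 5 libraries. Its interval also left out 0 in early replicate 2 (0.17 to 0.35), early replicate 3 (-0.32 to -0.09) and middle replicate 1 (-0.39 to -0.06). Unequal positions alone are thus not special to middle replicate 3. Lower depth is argued against as well, since this library had 6096805 reads and middle replicate 1 had 5305983, and a candidate explanation that stays open, as a hypothesis, is that these juveniles had gone less far through the same stage change: rises (0.78) and falls fell short by like amounts on the log2 scale, with a difference of 0.02 (-0.10 to 0.14), but this difference lay between -0.11 and 0.07 in the other 5 libraries too and does not single out that explanation.

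Among all calls short gene models were more often higher and long ones more often lower in middle J2, but among calls of at least 2-fold rises were 56.5% in the shortest and 56.4% in the longest band, where a shift as small as this one could hardly turn a direction. The trend was not the whole source of the calls, since 87.4% of them remained, with the same direction, after it was removed in each library. A slope on log2 length was taken of each library's deviation from the row mean of log2(FPKM + 1) over the 6 libraries. It was 0.0110 to 0.0305 in early and -0.0285 to -0.0164 in middle libraries. The gap of 0.0274 between the stages was larger than the range within either. This split restates the trend between the stages, and 3 against 3 libraries part fully in 10% of groupings by chance. A length bias that varied between libraries whatever their stage is therefore not excluded. The mean slopes differed by 0.0444, and their opposite signs follow from the centring, so only differences between libraries can be read from them. A length bias of library preparation that followed the stages and a shift in the animals towards short transcripts cannot be told apart here, because the labels give no preparation batch.

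Rows with consecutive ID numbers changed together. Over 10079 such pairs the log2 fold changes correlated at r = 0.215 across rows, against at most 0.031 in 1000 shuffles of the rows, which argues against chance pairing. The correlation was 0.053 for IDs 2 apart and 0.018 for IDs 3 apart. The deviations of replicates from their stage mean also correlated between neighbours (0.102 in early, 0.110 in middle J2). These deviations were not shuffled, and a shift of a whole library would make any pair of rows correlate. Whether the link goes beyond the stage change is therefore left open. Both rows were called with at least a 2-fold change in 119 pairs, against at most 62 in the shuffles, and 101 of these pairs moved in the same direction. If consecutive numbers mark neighbouring genes, which was not examined here, neighbours may vary together or be recent copies. Reads shared between similar models stay open as well: pairs over 4-fold apart in level still gave r = 0.157, against at most 0.043 in the shuffles, but stray reads from the higher row could give this too.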
